A study of Mus musculus with 3 samples.

How the data were processed

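RNA was extracted with a column kit, enriched for polyadenylated transcripts and made into barcoded Illumina libraries, per the labels' protocols. The medium was DMEM with 20% FBS. Each of the 3 libraries came as a table of deposited FPKM values (fragments scaled by transcript length and by mapped fragments) with a lower and an upper 95% bound, a status and a locus per gene. Per the submitters' processing notes, TopHat, Cufflinks and FastQC were used with the mouse build mm9. Versions, settings, strand and the annotation are not given in the sources used here. FPKM divides by library size and transcript length, so a few very abundant genes can shift all others, and a gene's value depends on how Cufflinks shares fragments between overlapping models. A table of the whole series held the same deposited FPKM values for the 3 libraries, equal in all 23807 rows. Its washout columns are headed with the word cont and the time; what cont stands for is not given in the sources used here, and they were matched to libraries by the time in the titles.

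Each library had 23807 rows and 23298 symbols, of which 320 rows had a low-data status. Values of rows with the same symbol were summed, because duplicate symbols were not in the same order in every file. Deposited FPKM lay outside its own deposited bounds for 21.5%, 19.9% and 20.0% of rows above 1 FPKM in the control, 1 h and 6 h libraries. For that reason the bounds were used for their width and for overlap, not as limits around the value. Overlap still depends on where the bounds lie, so calls of bounds apart share this weakness. Bounds counted as apart in either direction, and the direction of a gene was taken from its FPKM. Locus starts were counted from 0 in the files, since end minus start equalled the gene length of the reference annotation (GRCm38.p6, used for lengths and names only) for 9171 of 21275 symbols, and differed by 1 for 557. Starts are therefore printed with 1 added, on mm9.

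The depth was estimated from low values. For genes with 1 transcript longer than 1500 nt in GENCODE vM21, FPKM times length clustered at whole multiples of a step. Of 230, 217 and 220 low values, 70.4%, 67.3% and 65.9% lay within 0.15 of a whole number, where evenly spread values give 30%. The step was fitted to the same values from a preset starting window, so part of this clustering was built in. The steps correspond to about 23600000, 20700000 and 20900000 fragments. Ratios of low values gave a control 1.13 times as deep as the 1 h library and 1.12 times as deep as the 6 h library. These are estimates, because FPKM uses an effective length, so whole fragments were not recovered and no count test was run.

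Differences were computed as log2(FPKM + 1) in one library minus the other, which understates the difference of low genes. Genes with a mean of at least 1 FPKM over the 3 libraries were kept, 10464 in all, and those at least 2-fold apart on this scale were counted. Folds in the text are ratios of FPKM without the pseudocount, given for genes above 0. Their intervals combine the relative widths of both libraries' bounds. With 1 library per group there is no p-value, standard error or SD. For each of 29 gene lists the median difference was set beside the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. None of the 432 listed genes belonged to more than 1 list. The percentile among random lists describes these libraries only. Overlap of the 1 h and 6 h calls was set beside 100 simulations of unchanged libraries with the spread given by the bounds, and beside the overlap of independent lists.

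The groups, comparisons, gene lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 highest and 12 lowest genes with bounds that did not overlap at 1 h and at 6 h, short RNAs set apart, plus all Notch targets, Notch1 and up to 4 genes from every other list. At 1 h, 7 of the 12 highest and 11 of the 12 lowest were listed at 0 in some library, and at 6 h 8 and 12 were. An exact 0 can be a failed estimate in such files, since genes such as Hmgcs1 and Fdft1 were listed at 0 throughout. After the data had been seen, the 20 highest and 20 lowest genes above 0 in all 3 libraries were therefore named instead, and the genes listed at 0 are described with the other observations. Cdh15, Txnrd1, Snai2, Areg, Hbegf and a few list members were named because they belong to a count in the text. Of the short RNAs (microRNA, small nucleolar and similar symbols), 84 were kept by the filter. At 1 h 21 of them were at least 2-fold higher and 29 lower, and at 6 h 18 and 21.

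Alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 FPKM, rescaling to a median ratio of 1 or to a common upper quartile, the series table, the highest row per symbol, only rows with status OK, a 1.5-fold threshold, leaving out each list's largest member, and random lists not matched on expression. Setting each alternative median beside random lists redrawn under that setting was added after the data had been seen. GC content and length were taken from GENCODE vM21 transcripts for 9764 genes, 94.2% of those above 0. The procedure was tested on simulated libraries built from the real means and bounds with 200 genes changed, all with a mean of at least 5 FPKM. Recovery of genes below that mean and spread between cultures were thus not tested. A 1.5-fold change lies below the 2-fold threshold, so few such genes could be called. In the simulation of 1 h against control with 10464 genes, 100% of genes changed 4-fold were called, 0% of genes changed 1.5-fold and 0.21% of unchanged genes, and 5% of unchanged lists fell outside the central 95%. For 6 h against control these shares were 100%, 0%, 0.23% and 7%, and for 6 h against 1 h 100%, 0%, 0.15% and 1%. The work used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.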

Results

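The series profiled polyadenylated RNA from C2C12 cells, a mouse myoblast line, carrying a human NOTCH1 that lacks the extracellular domain. Such a receptor needs no ligand, and its release from the membrane depends on gamma-secretase, the protease that DAPT inhibits. The cells were cultured in 10 uM DAPT, which was removed from the cultures of interest 1 h or 6 h before collection. There were 3 libraries, 1 per group: a control labelled as without treatment, 1 library at 1 h after washout and 1 at 6 h. The series table heads the control's column untreated, and the labels do not say outright whether the control stayed in DAPT until collection. If it never had DAPT, differences from it also include the earlier DAPT exposure of the washout cultures. The washout libraries are taken as such from their titles, while the series table heads the matching columns with the unexplained word cont and the time. Because each group was a single library, no test between conditions was possible, and no difference below has a replicate check. The intervals given with folds come from the widths of the deposited 95% bounds of each library, and cover counting and read assignment within a library only. Depth estimated from the spacing of low FPKM values was about 23600000 fragments for the control, 20700000 at 1 h and 20900000 at 6 h. In these libraries 3 fragments on a 1 kb transcript were worth 0.127, 0.145 and 0.144 FPKM.

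The comparison of 1 h washout with the control asked which transcripts differed from the control soon after DAPT was removed. Hes1, a transcriptional repressor directly controlled by Notch, stood at 254 FPKM at 1 h and 22.5 FPKM in the control, 11.3-fold higher (10.1 to 12.6). Its locus in the files is chromosome 16, 30065443 to 30067882 (mm9). Hes1 was the 1 gene among 12 expressed canonical Notch targets that was at least 2-fold higher, and 0 were at least 2-fold lower. Myc was 1.99-fold higher (1.87 to 2.12), at 103 against 51.8 FPKM, and the ligand gene Efnb2 was 1.71-fold higher. The classical targets Hey1, Heyl and Nrarp had 3.52, 0.603 and 0.336 FPKM at 1 h, beside 1.87, 0.316 and 0.362 FPKM in the control. Jag1 had 4.26 against 4.63 FPKM. The median log2 difference of the 12 targets was 0.36, above the central 95% of random lists matched on expression (-0.16 to 0.12). That median was 0.57 with a pseudocount of 0.1 and 0.20 with a pseudocount of 5. Of the 16 listed targets, Hes5 and Dtx1 were listed at 0 in every library and Hes7 and Hey2 stayed below 1 FPKM.

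Immediate early genes, which cells transcribe within minutes of a stimulus without new protein synthesis, made up most of the 20 highest genes at 1 h among those above 0 in all libraries. Of 38 expressed members, 30 were at least 2-fold higher at 1 h than in the control and 0 were at least 2-fold lower. Their median log2 difference was 1.48, against a random range from -0.11 to 0.03. The nuclear receptor gene Nr4a1 had 186 FPKM at 1 h and 1.87 FPKM in the control, 99.3-fold higher (79.5 to 124). Egr1, a zinc finger transcription factor gene, stood at 681 against 18.1 FPKM, 37.6-fold higher (34.8 to 40.5). Its relative Egr2 was 37.1-fold higher (30.1 to 45.8), and Egr3 26.2-fold. Fos and Fosb, which encode AP-1 subunits, had 18.6 and 16.9 FPKM at 1 h, with 0.475 and 0.415 FPKM in the control. The phosphatase gene Dusp1 was 11.2-fold higher (10.2 to 12.2), Btg2 20.2-fold, and Zfp36, whose product destabilises AU-rich mRNAs, 7.35-fold.

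Other groups were higher at 1 h as well. Among 15 SRF and YAP targets 3 were at least 2-fold higher, and the list median was 0.17 (random range -0.15 to 0.03). These were Ctgf (1189 against 213 FPKM, interval of the fold 5.44 to 5.73), Cyr61 (4.52-fold) and Ankrd1 (3.25-fold). BMP and TGF-beta targets had a median of 0.62 over 10 expressed genes, 2 of them at least 2-fold higher, and of 0.40 without the member that differed most, still above its range. Id1, an inhibitor of differentiation, was past 2-fold at 266 against 124 FPKM. Circadian clock genes had a median of 0.46 over 11 genes, which was 0.28 without Dbp and 0.19 with a pseudocount of 5, each still above its random range. In that list Bhlhe40 was 3.05-fold, the period gene Per1 2.82-fold and Nr1d1 2.28-fold higher, while Dbp was listed at 0 in the control and had 3.35 FPKM at 1 h. Sgk1, a serum- and glucocorticoid-responsive kinase gene, was 5.68-fold higher (5.40 to 5.98), and Tsc22d3 2.35-fold. The median of the 6 expressed glucocorticoid-responsive genes was 0.43, above its random range (-0.22 to 0.16), and 0.19 without Sgk1, inside that of the remaining 5 genes (-0.25 to 0.21).

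Further positive medians at 1 h were those of hypoxia and glycolysis genes (0.30, with 2 of 13 at least 2-fold higher) and of unfolded protein and amino acid stress genes (0.27, 2 of 17). The members past 2-fold were Ankrd37 and Vegfa in the former list, and Chac1 and Trib3 in the latter. G2/M cell cycle genes had a median of 0.24 with 0 of 21 past 2-fold. Extracellular matrix genes had 0.20, with Thbs1 2.77-fold higher. NF-kB targets had 0.13, with Nfkbiz, Cxcl1 and Il6 past 2-fold among 12 genes. Myogenic regulators had 0.20 over 9 genes. Myf5, a muscle determination factor gene, was 2.32-fold higher (2.03 to 2.65), at 26.4 against 11.4 FPKM. In the main setting the medians of these lists lay above the central 95% of their random lists. The myogenic median was 0.12 without Myf5, inside the range of the remaining 8 genes (-0.20 to 0.15). NF-kB targets also came inside their range without Il6 and with a mean of at least 5 FPKM, at a median of 0.07 in both, and at the 97.2 percentile when random lists were not matched on expression.

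Among the lowest genes above 0 in all libraries at 1 h was Hmox1. This gene, which encodes the haem-degrading enzyme haem oxygenase 1, had 124 FPKM at 1 h and 515 FPKM in the control, 4.14-fold lower, with a ratio of 0.242 (0.231 to 0.253). Srxn1, the sulfiredoxin gene, had 106 against 352 FPKM, a ratio of 0.302 (0.290 to 0.315). Glutathione transferase gene Gsta4 had 219 against 642 FPKM, and the quinone reductase gene Nqo1 72.0 against 186 FPKM. Gclm, a subunit of the enzyme that starts glutathione synthesis, had 62.1 against 159 FPKM. Slco4a1, Layn, Foxq1 and the iron exporter gene Slc40a1 also belonged to the 20 lowest genes, with ratios of 0.087, 0.285, 0.171 and 0.125. Sterol synthesis genes had a median of -0.42 over 16 genes (random range -0.14 to 0.10), and only Lss passed 2-fold, at 4.26 against 10.5 FPKM. In the same list Hmgcs1 and Fdft1 were listed at 0 in every library. Medians below the random range were also found for 5 muscle contractile genes (-0.37), 17 ribosome biogenesis genes (-0.16) and 22 ribosomal protein genes (-0.15), with 0 members past 2-fold in each. The contractile median came inside its range with a pseudocount of 5 (-0.20) and, over 2 genes, with a mean of at least 5 FPKM (-0.16). The ribosome biogenesis median came inside it without Polr1b (-0.14).

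Of 10464 genes with a mean of at least 1 FPKM, 137 were at least 2-fold higher and 87 at least 2-fold lower at 1 h than in the control. The deposited bounds of the 2 libraries did not overlap for 116 of the former and 60 of the latter. Of the 25 lists with at least 2 expressed genes, 12 medians lay above and 4 below the central 95% of their random lists. Lists of independently drawn genes would give about 0.63 on each side. Genes of 1 list can vary together between cultures, which that number leaves out. Lists inside that range at 1 h were Notch pathway components, G1/S cell cycle, interferon-stimulated, heat shock, p53 target and housekeeping genes, and the osteoblast, adipocyte, and fibroblast and mural cell markers. Without Cebpa the adipocyte median, -0.004 with it, was 0.31, just above the range of the remaining 3 genes. With short RNAs and genes listed at 0 in some library left out, a choice made after seeing the data, 94 genes were higher and 43 lower. With a pseudocount of 5 the counts were 90 and 57, and with 0.1 they were 156 and 143. At a 1.5-fold threshold the direction of the excess turned, with 318 higher and 366 lower.

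**Figure D1:**
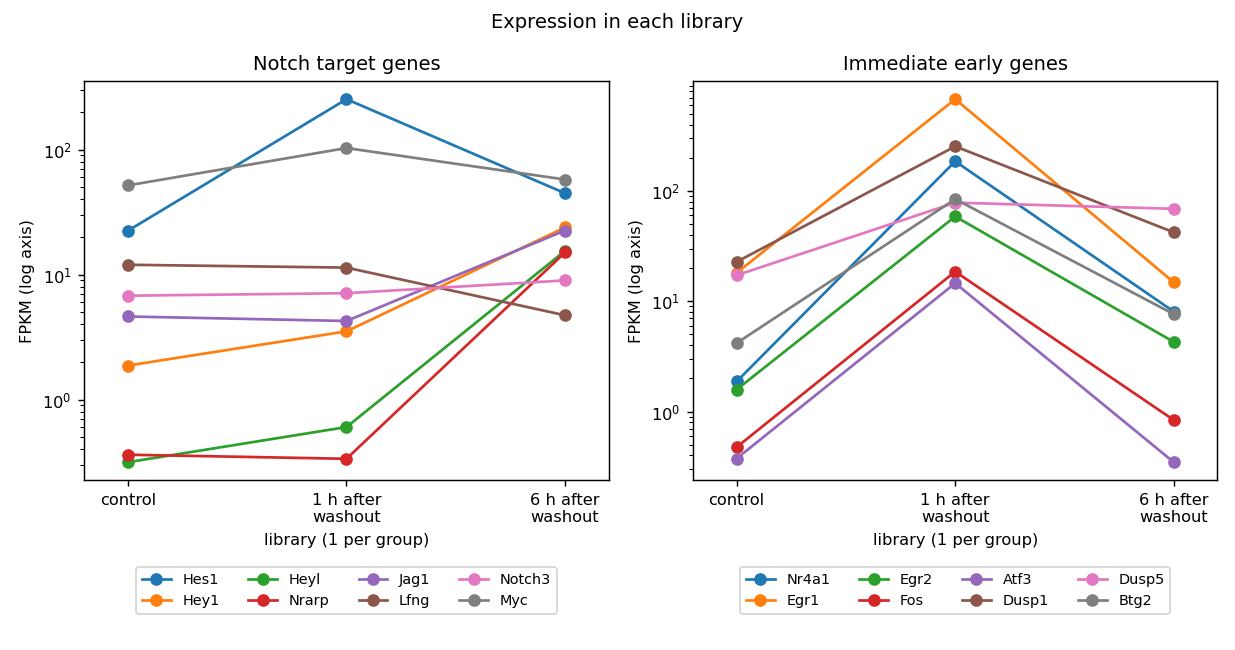
FPKM on a log axis in the 3 libraries, for 8 Notch targets (left) and 8 immediate early genes (right); each point is 1 library and lines join the values of a gene across separate cultures. Hes1 is highest at 1 h (254 FPKM), whereas Heyl and Nrarp reach 15.5 and 15.1 FPKM at 6 h.

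In the 6 h library, set against the control to follow the later state, classical Notch targets stood out. Heyl, a HES-related repressor gene, had 15.5 FPKM at 6 h and 0.316 FPKM in the control, 49.1-fold higher (35.2 to 68.4). Nrarp, a feedback regulator of Notch signalling, had 15.1 against 0.362 FPKM, 41.6-fold higher (27.4 to 63.0). Hey1 was 12.7-fold higher (9.93 to 16.3), at 23.9 against 1.87 FPKM, and the ligand gene Jag1 4.88-fold higher (4.36 to 5.46), at 22.6 against 4.63 FPKM. These 4 genes, of 12 expressed targets, were at least 2-fold higher, and 1 was at least 2-fold lower. That gene was Lfng, a glycosyltransferase gene, at 4.73 against 11.99 FPKM with a ratio of 0.394 (0.320 to 0.486). Hes1 was at 44.8 FPKM, a log2 difference of 0.97. The list median was 0.57, above its random range (-0.18 to 0.08). Heyl lies on chromosome 4 at 122910799 to 122927113, Nrarp on chromosome 2 at 25036278 to 25038852 and Hey1 on chromosome 3 at 8663359 to 8667038 (mm9).

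Endogenous Notch1 had 3.65 FPKM in the control, 4.32 at 1 h and 6.01 at 6 h. Fragments of the human transgene could align to this mouse gene, and the files do not separate them. The 24 expressed Notch pathway components had medians of -0.02 at 1 h and -0.09 at 6 h, both inside the random range, and 0 members were 2-fold apart from the control at either time. The former median became 0.01 under both rescalings.

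Inhba, Il6, Pkp1, Il11, Rgs16, Has2 and Itgb3 were among the 20 highest genes above 0 in all libraries at 6 h. Inhba, which encodes an activin subunit, had 493 against 66.3 FPKM, 7.44-fold higher (7.02 to 7.89). The cytokine gene Il6 had 10.0 against 0.487 FPKM, and Il11 5.54 against 0.103 FPKM. Has2, a hyaluronan synthase gene, was 5.18-fold, the desmosomal plakophilin gene Pkp1 7.11-fold and the integrin gene Itgb3 4.43-fold higher. BMP and TGF-beta targets had a median of 0.25 over 10 genes, with 1 at least 2-fold higher and 1, Atoh8 (4.08 against 11.2 FPKM), at least 2-fold lower. Extracellular matrix genes had a median of 0.17 over 19 genes, 2 of them past 2-fold, Tnc (2.62-fold) and Col5a3 (2.21-fold). With the deposited bounds apart, 11 of the 19 were higher and 6 lower. Both list medians lay above their random ranges (-0.16 to 0.08 and -0.10 to 0.04).

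Muscle regulators as a group were close to the control at 6 h. The median of 9 myogenic regulators was -0.05, inside the random range, and became 0.01 when rescaled to a median ratio of 1. Cdh15, the M-cadherin gene, was the 1 member at least 2-fold higher, at 87.0 against 27.4 FPKM. Only 5 of 26 contractile genes were expressed, and of these Tnnt2 was 4.29-fold higher (3.77 to 4.88). Immediate early genes had a median of 0.30 over 38 genes, and 0.11 with a pseudocount of 5, above the random range in both. In this list 5 genes were at least 2-fold higher: Egr2, Nr4a1, Dusp5, Dusp6 and Hbegf. Ribosome biogenesis genes had a median of 0.20 over 17 genes and 0 past 2-fold. Small marker lists also lay outside their random ranges, namely 3 fibroblast and mural cell markers (median 0.57, and 0.07 without Cspg4), 2 osteoblast markers (0.52) and 4 adipocyte markers (-0.48, and -0.26 without Cebpa). Without Cspg4 or Cebpa the first and last of these came inside their ranges. The adipogenic transcription factor gene Cebpa was at 2.76 against 11.3 FPKM. G1/S cell cycle genes had a median of -0.18 over 18 genes, below the random range (-0.13 to 0.06), with 0 past 2-fold, and of -0.12 when rescaled to a median ratio of 1, still below its range.

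Lower at 6 h were the glutamate transporter gene Slc1a3 (1.11 against 6.64 FPKM, ratio 0.167, 0.133 to 0.209), Ranbp3l, Dhrs3 and Gas1. The growth factor gene Fgf7 had 8.11 against 22.7 FPKM, and Pdk4, a kinase gene that restrains pyruvate oxidation, had 10.7 against 27.9 FPKM. Hmox1 had 518 FPKM at 6 h and 515 FPKM in the control, and Srxn1 386 and 352 FPKM.

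Of the same 10464 genes, 113 were at least 2-fold higher and 66 at least 2-fold lower at 6 h than in the control, and the deposited bounds were apart for 95 and 46 of them. Of the 25 list medians, 7 lay above and 2 below the central 95% of their random lists. Inside it, besides the Notch pathway and myogenic lists, were SRF and YAP targets, G2/M cell cycle, NF-kB target, interferon-stimulated, sterol synthesis, stress, heat shock, hypoxia and glycolysis, circadian, glucocorticoid-responsive, p53 target, ribosomal protein, housekeeping and muscle contractile genes. Some of these lay outside their range in another setting: NF-kB targets at -0.30 with a mean of at least 5 FPKM and -0.21 without Il6, p53 targets at 0.16 and 2 contractile genes at 0.92 with that mean (main medians of the opposite sign, -0.02 and -0.20), and sterol synthesis genes at -0.14 with a pseudocount of 5. Without short RNAs and genes listed at 0 in some library, the counts were 77 and 30, with a pseudocount of 5 they were 69 and 40, and with 0.1 they were 129 and 116. The excess turned here too at 1.5-fold, with 245 higher and 290 lower.

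**Figure D2:**
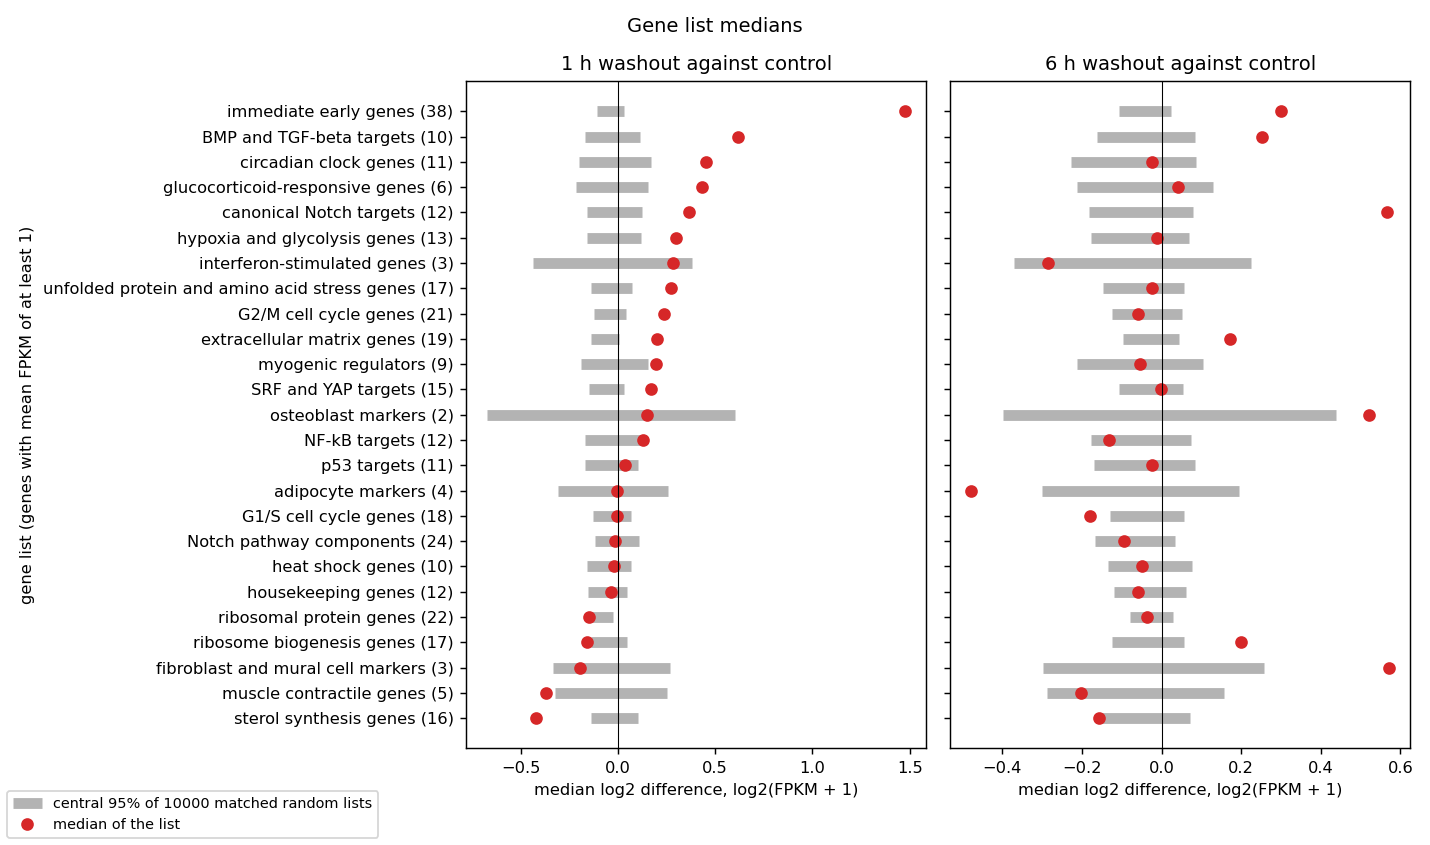
Median log2 difference of each gene list (red points) in the comparisons of 1 h and 6 h washout with the control, beside the central 95% of 10000 random lists matched on mean expression (grey bars); the number of expressed genes is in brackets. Immediate early genes lie farthest from their bar at 1 h (1.48), and canonical Notch targets have a median of 0.57 at 6 h.

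Between the washout times, immediate early genes were lower at 6 h than at 1 h: 23 of 38 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -1.52 (random range -0.09 to 0.09). Hes1 was at 44.8 FPKM at 6 h and 254 FPKM at 1 h. Canonical Notch targets differed in both directions, with Heyl, Nrarp, Hey1 and Jag1 at least 2-fold higher at 6 h and Hes1, Lfng and Snai2 at least 2-fold lower. Their median was -0.01, inside its random range (-0.22 to 0.17), with values of -0.25 without Nrarp, below the range of the remaining 11 genes (-0.22 to 0.18), and 0.03 when rescaled to a median ratio of 1. Ribosome biogenesis genes (0.41) and sterol synthesis genes (0.40) were higher at 6 h than at 1 h, each above its random range with 0 members past 2-fold. Medians of circadian clock genes (-0.52, with -0.78 at a pseudocount of 0.1 and -0.32 at 5), NF-kB targets (-0.55) and BMP and TGF-beta targets (-0.48) lay below theirs. Txnrd1, the thioredoxin reductase gene, had 830 FPKM at 6 h and 256 FPKM at 1 h. In all, 154 genes were at least 2-fold higher and 178 at least 2-fold lower at 6 h than at 1 h, with the bounds apart for 130 and 165. Of the 25 list medians, 3 lay above and 11 below the central 95% of their random lists. With a pseudocount of 5 the gene counts were 78 and 94.

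Most genes 2-fold from the control at 1 h were near it at 6 h. Of the 137 higher at 1 h, 79 were within 0.58 of the control on the log2 scale at 6 h and 33 were also at least 2-fold higher at 6 h. Of the 87 lower at 1 h, 54 were back within that limit and 24 were also at least 2-fold lower. Another 73 genes were higher and 29 lower at 6 h and within 0.58 at 1 h. Without short RNAs and genes listed at 0, the overlaps were 15 higher genes of 94 and 77, and 2 lower genes of 43 and 30. The 15 included Inhba, Il6, Has2, Rgs16, Ctgf, Hbegf and Areg, and the 2 were Phospho1 and Slco4a1. Unchanged libraries simulated with the deposited bounds against the shared control gave mean overlaps of 0.21 and 0.25 genes on this set. The largest simulated overlap was 2 in each direction, as many as the lower genes observed. These simulations held the spread of the bounds only and made on average 1.05 higher and 0.92 lower calls at 1 h. Small overlaps were thus built in, and variation between cultures was not covered. Independent lists of the observed sizes would share 0.70 and 0.12. Over all 10464 genes the simulated overlaps were 3.63 and 4.48 genes, and independent lists would share 1.48 and 0.55. The simulated values started from each gene's mean, so values listed at 0 were not reproduced. The overlaps of 33 and 24 over all genes include such genes, and the simulation is no baseline for them. With a single control library that could not be split, part of the overlap may come from the shared control. Of the 30 immediate early genes at least 2-fold higher at 1 h, 18 were within 0.58 of the control at 6 h and 25 were under 2-fold.

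**Figure D3:**
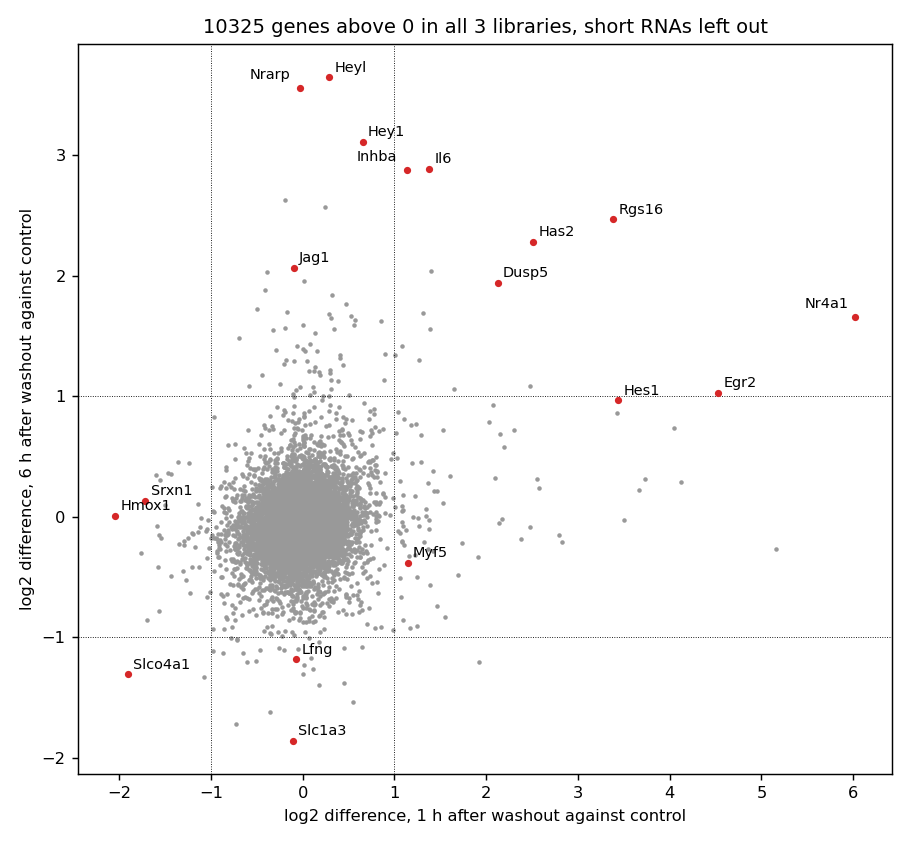
Log2 difference from the control at 1 h (horizontal axis) and at 6 h (vertical axis) for 10325 genes above 0 in all 3 libraries, short RNAs left out; each point is 1 gene, dotted lines mark 2-fold and named genes are in red. Nr4a1 lies far right (6.02), Heyl and Nrarp lie at the top near 0 at 1 h, and Hmox1 lies at the left (-2.04).

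No marker of endothelial (6 genes), epithelial (6 genes) or blood cells (6 genes) had a mean of at least 1 FPKM, and 1 of 5 neuronal markers, Tubb3, did. Among these 4 lists Krt19 reached 1.48 FPKM and Cd68 1.04 FPKM in a single library. The 12 housekeeping genes had medians of -0.03 at 1 h and -0.06 at 6 h. The latter became 0.00 when rescaled to a median ratio of 1. The median over all 10464 genes was -0.02 at 1 h, -0.06 at 6 h and -0.03 between them.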

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

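No paired analysis was possible because each group held 1 library. Leaving out short RNAs or genes listed at 0, and requiring bounds that do not overlap, were chosen after seeing the data. Counts are given as total, higher, lower. With a pseudocount of 5, 147, 90 and 57 genes passed at 1 h against control (main 224, 137 and 87), 109, 69 and 40 at 6 h against control (main 179, 113 and 66), and 172, 78 and 94 at 6 h against 1 h (main 332, 154 and 178). A larger pseudocount shrinks the differences of low genes by construction. With a pseudocount of 0.1 the lower genes numbered 143, 116 and 274 in the same order of comparisons. A 1.5-fold threshold passed 684, 318 and 366 genes at 1 h, 535, 245 and 290 at 6 h, and 1074, 491 and 583 between the times, so at 1 h and at 6 h the larger side became the lower one. With only genes above 0 in all 3 libraries, 51 were lower at 1 h, and at 6 h 111 were apart, 33 of them lower. Leaving out short RNAs too gave 137 apart and 43 lower at 1 h, and 107 and 30 at 6 h. The genes past 2-fold the same way at both times numbered 57, against 32 without short RNAs, 21 above 0 and 17 with both. These settings remove genes by construction. The Notch target median at 1 h (0.36) was 0.57 with a pseudocount of 0.1 and 0.20 with 5, and at 6 h it ranged from 0.46, without Heyl, to 0.63 when rescaled to a median ratio of 1. Other settings left every count within 1.5 times, and the series table moved nothing. At 6 h against 1 h the Notch target median (-0.01) was -0.25 without Nrarp. Random lists not matched on expression changed the side of 2 of 72 other percentiles, NF-kB targets at 1 h (97.2) and stress genes at 6 h against 1 h (2.995). Of 573 alternatives for the other lists, 19 moved a median by more than the half-width of its random range, and of 3240 for named genes 322 moved a difference by more than its counting interval. No list called, or named gene past 2-fold, in the main setting changed sign. The medians of 3 lists did so and left their random range: contractile genes (-0.20 to 0.92) and p53 targets (-0.02 to 0.16) at 6 h with a mean of at least 5 FPKM, and adipocyte markers at 1 h without Cebpa (-0.004 to 0.31). Among 150 rescaled list medians 27 changed sign or became 0, each within 0.1 of 0. Low values limit what can be read: below about 0.13 to 0.14 FPKM on 1 kb a gene rests on fewer than 3 fragments.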

Other observations

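All tests in this part were chosen after the result was seen, except that of overlapping gene models.

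C2C12 cells are used as myoblasts, yet Myod1 and Myog, which encode muscle-specifying transcription factors, had 0.189 and 0.337 FPKM in the control, 0.295 and 0.625 FPKM at 1 h, and 0 (as listed) and 0.310 FPKM at 6 h. Pax7 had at most 0.011 FPKM. Some other muscle-lineage genes were well above the floor in the control: Des, the intermediate filament gene, at 62.2 FPKM, Acta1 at 33.7 FPKM, M-cadherin gene Cdh15 at 27.4 FPKM and Myf5 at 11.4 FPKM. Of the whole lists, 9 of 16 myogenic regulators and only 5 of 26 contractile genes had a mean of at least 1 FPKM. Edn1, the endothelin gene, stood on opposite sides of the control at the 2 times, at 29.1 FPKM at 1 h, 6.95 in the control and 2.44 at 6 h. Id2 had 44.9, 24.4 and 12.5 FPKM in the same order.

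The low values of antioxidant genes at 1 h were followed with a list of NRF2 targets, the genes through which that transcription factor answers oxidative stress. The list was written after 6 of them had been noticed among the lowest genes. Of 25 further members 23 were expressed, 22 of them lower than the control at 1 h and 8 at least 2-fold lower. Their median was -0.67 (random range -0.13 to 0.03). At 6 h it was -0.12, still below its random range (-0.11 to 0.04), with 0 past 2-fold. Examples are Txnrd1 at 608, 256 and 830 FPKM in the control, 1 h and 6 h libraries, Gclc at 66.0, 28.1 and 60.2, and Sqstm1 at 624, 252 and 457.

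Technical explanations for the NRF2 pattern were weighed first. With the median of each GC bin subtracted, the median of the 23 members was -0.62, still below its random range, which argues against GC content as the whole cause. Without Gsta and Gstm genes, which share reads, the median of the remaining 21 of these members was -0.58, also below its random range. Ribosomal protein and housekeeping genes together had a median of -0.13 at 1 h, well above the members' -0.67. This argues against a general loss of abundant transcripts as the whole cause. A smaller fall was present, since 21 of 22 ribosomal protein genes were lower and 0 higher with bounds apart. What stays open, untested, is the release of gamma-secretase itself or a difference between separate cultures, such as fresh medium. DAPT exposure before the washout also stays open, if the control had none. A fall from the control's level that began at the washout would need short half-lives, even with transcription stopped at once. The longest possible were 0.49 h for Hmox1, 0.58 h for Srxn1, 0.65 h for Gsta4 and 0.73 h for Nqo1. Half-lives were not measured here, so these limits do not decide between the causes.

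Immediate early genes and Hes1 were higher at 1 h. GC content is argued against for the 38 immediate early genes, whose median was 1.53 after subtraction of GC bin medians (upper random limit 0.06). Hes1 alone had a difference of 3.54 after the same subtraction and 3.44 before. A medium change with 20% serum could induce such genes with no part for Notch, and Hes1 itself can respond to serum. SRF and YAP targets, which share no gene with the list, had a 1 h median at the 99.99 percentile of random lists, as a medium change would give. No library is labelled as having its medium changed without a washout, and how the control's medium was handled is not given. The medium change and the release of gamma-secretase therefore cannot be told apart at 1 h. Whether the Heyl, Nrarp, Hey1 and Jag1 levels at 6 h share this confounding was not tested.

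Of 102 expressed genes listed at 0 in 1 or 2 libraries, 47 were short RNAs and 55 were not, and 22 of the latter reached 10 FPKM elsewhere. Rps27 was listed at 0, 238 and 0 FPKM in the control, 1 h and 6 h libraries, Rpl26 at 0, 111 and 166, and Ddit3 at 43.8, 57.8 and 0. Failed estimates where gene models overlap are a likely cause: 54 of the 55, or 98.2%, overlap another gene in the files, against 17.4% of all expressed genes and an upper limit of 27.3% in random lists. Too few fragments would not depend on overlap, yet among the 49 with a known transcript length 98.0% overlap, above the limit of 28.6% in random lists matched on FPKM in the highest library times length. This argues against it as the whole cause. A biological difference in single genes stays untested, and the values at 0 are best not read as absence.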
